A study of Mus musculus with 11 samples.

How the data were processed

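Gene expression was measured on 11 one-colour Affymetrix whole-transcript arrays, each hybridised with biotin-labelled material from total RNA of mouse embryonic stem cells (ESCs). The labels place the arrays in 4 groups made of 2 genotypes and 2 media. The control is the E14 line, and the mutant cells are labelled Bmpr1a-/-. The groups are control in ESC medium (n = 3), mutant in ESC medium (n = 2, numbered 2 and 3), control after 3 days in N2B27 (n = 3) and mutant after 3 days in N2B27 (n = 3). The labels name 3 mutant lines but not the line on each array, and a mutant array numbered 1 in ESC medium is not analysed here. They do not say that the arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

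The deposited table holds log2 values per transcript cluster (the array's unit for 1 gene or part of a gene), made by the authors with RMA in Affymetrix Expression Console 1.2, per the submitters' processing notes. RMA corrects background, normalizes between arrays by quantiles and summarises probes. That the log base is 2 follows from the usual output of RMA, since no label states it. The 28815 clusters have no missing values, and the values run from -5.22 to 6.42. Each cluster had been centred on a baseline of its own, and the labels do not say how. In 55.8% of the clusters at least 1 array sits at exactly 0, and in 21.0% the median over these 11 arrays is exactly 0. All arrays lie above 0 in 16 clusters and below 0 in 15, so the baseline is not always the median of these arrays. Differences between arrays keep their meaning after this step, while the brightness of a gene is lost. No value can therefore be called high or low in absolute terms, and the number of arrays limits the precision.

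Clusters were named through the platform annotation supplied with the table. It gives 1 gene symbol for 21780 clusters, several for 1605 and none for 5430, and only clusters with 1 symbol were used. Of these, 21689 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez identifier, no symbol had to be changed, and 91 kept the annotation's symbol. The build used to design the array is not given in the sources used here, so the gene table served only for names, for the chromosome of a gene and for the order of neighbouring genes. The plan had been to keep the brightest cluster of a gene and to try a filter on dim probes. Neither can be done on centred values, so the clusters of a gene were averaged, which left 19935 genes, 18937 of them with 1 cluster and 998 with several.

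Group means were fitted jointly over the 4 groups with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. The fit has 7 residual degrees of freedom and a prior worth 3.02. Differences between groups are log2 differences with the moderated standard error (SE), and all tests are two-sided. A gene was called where its Benjamini-Hochberg adjusted p was under 0.05 over all genes tested. The comparisons were mutant against control in each medium, N2B27 against ESC medium in each genotype, and the interaction, which is the genotype difference in N2B27 minus that in ESC medium. The groups, comparisons, tests, gene lists and rule for naming genes were fixed before the data were examined.

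There were 22 gene lists, of pluripotency states, germ layers, other cell types that such cultures could hold, signalling targets, metabolism, imprinting and proliferation. Each was tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The same test with an estimated correlation, and fry, were alternatives. With an estimated correlation, 2 list calls held, both in the interaction. Members of a list were also counted with p adjusted over the list alone. Several genes stand in more than 1 list, and many genes of the differentiation and cell type lists are also expressed by ESCs.

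The genes named are the 10 largest increases and the 10 largest decreases of each pairwise comparison among called genes whose groups do not overlap, and the 5 and 5 largest of the interaction. From each list the rule adds up to 4 called members with the largest differences, or the 2 largest where none was called, and some of these are not named here. A set of 22 genes is given whatever their values. Of these, 20 were measured, while Cdkn1a and the gene for brachyury were not analysed here. Predicted genes, olfactory and vomeronasal receptors, small RNAs and symbols on several loci (2858 in all) were tested but not named. Genes of the Y chromosome, Xist in ESC medium and a few genes of the closing section were chosen after their values were seen.

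Shared sample numbers were checked for pairing by the correlation across genes of the arrays' deviations from group means. By number it was 0.256, 0.430 and 0.158 for genotype in N2B27 and 0.138, 0.181 and 0.131 for medium in control, all above 0.1. In these comparisons the numbers were taken to pair the arrays, on the values alone, but the main tests are unpaired. The other comparisons share only 2 numbers. Arrays of a group were compared in the order control ESC medium, mutant ESC medium, control N2B27 and mutant N2B27. Correlations of centred values, which grow with distance from the baseline, were 0.693 to 0.840, 0.921, 0.738 to 0.852 and 0.277 to 0.655. SDs of array differences were 0.125 to 0.217, 0.163, 0.139 to 0.195 and 0.231 to 0.332. At most 161 clusters were identical in a pair.

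The alternatives were a fit of the compared groups alone, the sample number as a replicate block, a random block of genotype and number (duplicateCorrelation, consensus 0.158), arrays centred on their median, cyclic loess, a trended and robust prior, array weights, stricter thresholds, and leaving out each array in turn. Added after the data had been seen were fits without chromosomes 8, X and Y (1712 genes), with genes of 1 cluster, with each cluster on its own, and list tests under both rescalings. Cyclic loess and the trended prior use the mean of a gene over the arrays as its brightness, which centred values do not give.

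The pipeline was tested on simulated data with known changes placed among 19935 genes. Of the genes changed by 1 on the log2 scale, it recovered 86.6% for mutant against control in ESC medium, 92.5% for the same in N2B27, 95.5% for the medium in control, 94.0% for the medium in mutant and 74.6% for the interaction. For changes of 0.5 the shares were 59.7%, 59.7%, 56.7%, 52.2% and 26.9%. Correlations across genes carry no p-value because genes are not replicates. For comparisons that share control arrays, 100 simulated unchanged groups gave the covariance from sharing alone. Plots were drawn with matplotlib 3.10.9.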

Results

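The series profiled mouse embryonic stem cells (ESCs) of the E14 line and ESCs labelled Bmpr1a-/-, which lack a type I receptor for bone morphogenetic proteins (BMPs). Cells of both genotypes were grown in ESC medium or for 3 days in N2B27, a serum-free medium in which ESCs leave the pluripotent state, often along a neural route. The 11 arrays form 4 groups, with 3 control and 2 mutant arrays in ESC medium and 3 control and 3 mutant arrays in N2B27. Expression is given as log2 values relative to a baseline of each gene, so values can be compared between groups but not between genes. The number of arrays limits the precision. The first principal component, with 63.4% of the variance, separated the media, and the second, with 11.5%, placed all control arrays between 7.75 and 13.4 and all mutant arrays between -18.4 and -9.45. On the third, with 7.76%, mutant replicate 2 in N2B27 stood apart at 22.3, with the other 10 arrays between -12.0 and 11.2. The root mean square deviation from the group mean was 0.185 for this array and 0.0774 to 0.155 for the others.

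Bmpr1a itself read 0.37, 0.16 and 0.25 in the control arrays in ESC medium and -0.03 and 0.00 in the mutant arrays. In N2B27 it read 0.61, 0.68 and 0.76 in control and 0.15, -0.14 and -0.05 in mutant. Every mutant array thus lay below every control array. The log2 difference between genotypes was -0.27 (SE 0.10, adjusted p = 0.145) in ESC medium, where the call was not made, and -0.70 (SE 0.09, adjusted p = 0.00211) in N2B27. In ESC medium the gene was called under cyclic loess, with -0.72 (adjusted p = 0.00237). That setting takes the mean of centred values for brightness, which they do not give, so the call is weak support. The labels do not say which part of the gene was deleted, so a whole-gene value can stay high in mutant cells and is a weak check of the labels.

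The cell lines also differed in sex-linked transcripts and on chromosome 8. Eif2s3y, a Y-linked translation factor gene, read 0.37 to 0.72 in the 6 control arrays and -3.73 to -3.54 in the 5 mutant arrays. Of 9 Y-linked genes measured, Eif2s3y, Uty and Uba1y were called lower in mutant cells in ESC medium, and the first 2 in N2B27. Eif2s3y differed by -4.18 and -4.20. Uty, a demethylase gene, had -3.12 and -2.67 and Uba1y -0.64 and -0.09. Kdm5d, Srsy, Sry, Usp9y and Zfy2 differed by -0.06 to 0.06 in both media and Zfy1 by -0.48 and -0.20, none called. In ESC medium, Uba1y was not called without mutant replicate 2 (0.122) or 3 (0.0613), and Zfy1 was under cyclic loess (0.0321) and with array weights (0.0356). Hprt, the X-linked purine salvage gene, was lower in control by 5.59 (SE 0.17, adjusted p = 8.94e-08) in ESC medium and 5.03 (SE 0.15, adjusted p = 1.26e-07) in N2B27. Genes of chromosome 8 stood above those of the other autosomes in mutant cells by a median of 0.130 in ESC medium, with 150 of 961 genes higher and 10 lower, and by 0.171 in N2B27, with 242 higher and 2 lower. Genes of the X chromosome stood 0.101 higher in ESC medium, with 163 of 742 higher and 11 lower, and 0.0279 higher in N2B27, with 72 higher and 16 lower. The camera adjusted p was 2.79e-15 and 3.81e-18 for chromosome 8, or 0.0529 and 0.0636 with an estimated correlation. It was 7.5e-16 and 0.0327 for the X, or 0.00116 and 0.24 with an estimated correlation. These tests by chromosome were not planned. Across all genes, 313 of the 615 higher and 24 of the 609 lower calls in ESC medium were on chromosomes 8, X and Y, and in N2B27 314 of 817 and 20 of 327 were.

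**Figure D1:**
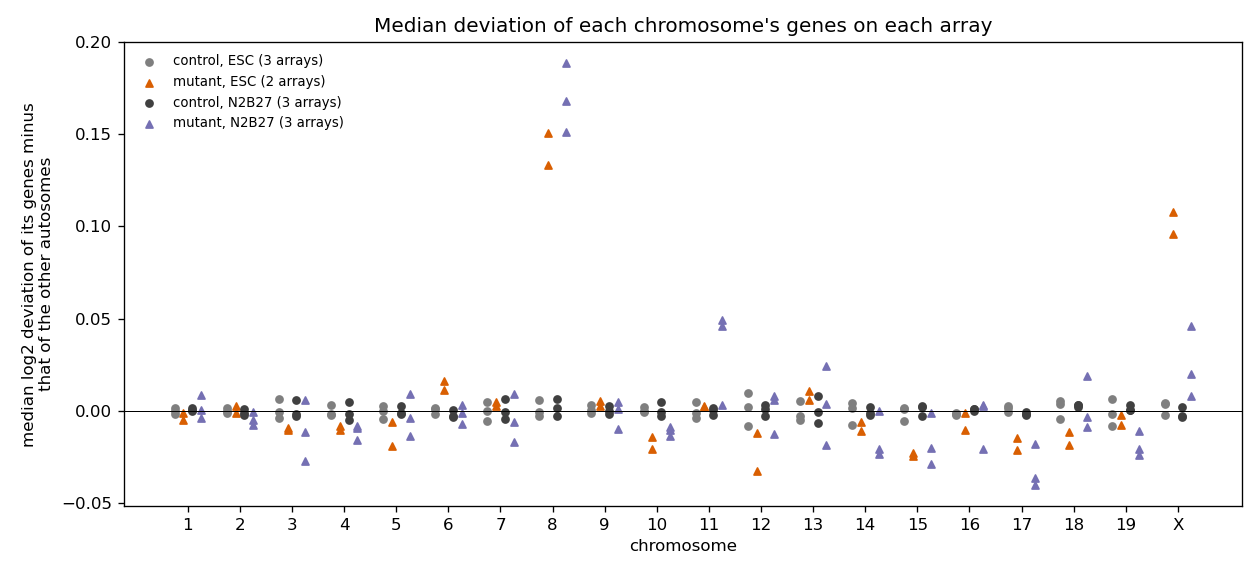
Median deviation of the genes of each chromosome from the control mean of the same medium, less that of the other autosomes, on the log2 scale; each point is 1 array and colours give the 4 groups. Chromosome 8 lies between 0.133 and 0.189 on the 5 mutant arrays, and the X chromosome at 0.0958 and 0.108 on the mutant arrays in ESC medium, while no autosome of a control array exceeds 0.00942. Control arrays lie near 0 by construction, and no other autosome of a mutant array exceeds 0.0493.

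How the cells labelled Bmpr1a-/- differ from E14 cells in ESC medium was addressed by mutant (n = 2) against control (n = 3). Every mutant array also differs from every control array in cell line, Eif2s3y and chromosome 8 values. No genotype difference given here, in either medium or in the interaction, can therefore be told apart from a difference between the lines. Id2 and Id3, inhibitors of differentiation and direct targets of BMP signalling, fell in mutant cells with log2 differences of -1.81 (SE 0.28, adjusted p = 0.00514) and -0.78 (SE 0.20, adjusted p = 0.0495). Id1 differed by -0.53 (SE 0.14, adjusted p = 0.0502). Of the 19 BMP-SMAD targets measured, these 2 fell and 17 did not pass, while 4 were lower adjusted over the list alone. The list's camera adjusted p was 0.0195, or adjusted p = 0.427 with an estimated correlation. Of 31 components of the BMP and Activin pathways, Acvr1 and Acvr2b, both receptor genes, fell (-0.45 and -0.41), the same 2 adjusted over the list alone (median -0.15, adjusted p = 0.00608, or adjusted p = 0.284 with an estimated correlation). The call of Id2 was lost without mutant replicate 2 (adjusted p = 0.0528) or 3 (0.0507), that of Id3 without any 1 of the 5 arrays (0.0721 to 0.36), and that of Acvr2b likewise (0.0876 to 0.323) and under cyclic loess (0.262). With a trended prior and without chromosomes 8, X and Y, Id3 (0.0754 and 0.0618) and Acvr2b (0.0841 and 0.0538) were not called, nor was Acvr2b with median centring (0.0523). Id1 passed without control replicate 1 (0.0275), with the compared groups alone (0.0449), with median centring (0.0428), under cyclic loess (0.01) and with array weights (0.00241). The BMP-SMAD list did not pass without mutant replicate 3 (0.176).

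In the same medium, Pramel6 and Pramel7, members of a gene family active in the early embryo and germ line, rose in mutant cells by 3.58 (SE 0.13, adjusted p = 3.28e-07) and 3.40 (SE 0.15, adjusted p = 1.51e-06). Of 19 germline genes, 9 rose and none fell, among them Sycp1, of the synaptonemal complex, by 1.40 and the ribosomal protein gene Rpl10l by 1.36, and 9 were higher and 3 lower adjusted over the list alone. The list median was 0.37 (camera adjusted p = 3.82e-05, or adjusted p = 0.284 with an estimated correlation), and 3 of the 9 genes, Taf7l, Rhox6 and Rhox9, lie on the X. Without chromosomes 8, X and Y, 6 of 16 rose (adjusted p = 0.001), while under cyclic loess the list and Rpl10l were not called (adjusted p = 0.161 for the list). Of the 5 genes measured from the 2-cell-like list, none passed and 1 was higher adjusted over the list alone (median 0.63, adjusted p = 0.00525, or adjusted p = 0.391 with an estimated correlation), and its direction turned under cyclic loess (adjusted p = 0.183). Without mutant replicate 2 its adjusted p was 0.0718.

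The naive pluripotency list leaned upward in mutant cells in ESC medium, which turned under cyclic loess, and the epiblast list downward. Of 21 naive genes, 5 rose, 16 did not pass and 7 were higher adjusted over the list alone (median 0.47, adjusted p = 1.8e-06, or adjusted p = 0.299 with an estimated correlation), with adjusted p = 0.0892 after that turn. Dppa3, a maternal factor, rose by 0.88 and Tcl1, an AKT cofactor, by 1.26, the latter turning to -0.07 under cyclic loess. The transcription factor genes Zfp42, on chromosome 8, and Klf4 rose by 0.88 (SE 0.22, adjusted p = 0.0416) and 0.64 (SE 0.16, adjusted p = 0.039), and turned to -0.29 and -0.49 under cyclic loess. Both calls were lost without control replicate 2 or 3 or either mutant replicate, with adjusted p from 0.105 to 0.323. The same held with the compared groups alone (0.0559 for Zfp42 and 0.123 for Klf4) and with a trended prior (0.0786 and 0.116). Nanog, Esrrb, Sox2 and Pou5f1 differed by 0.47, 0.31, 0.19 and 0.10, none called, though Nanog passed with the compared groups alone (adjusted p = 0.0163). Of 19 formative and epiblast genes, 5 fell and 7 were lower adjusted over the list alone (median -0.41, adjusted p = 4.13e-06, or adjusted p = 0.284 with an estimated correlation). Grhl2, an epithelial transcription factor gene, fell by 0.70 (SE 0.09). Fgf5, Otx2 and Dnmt3b differed by -0.42, 0.03 and -0.41, none called, and Dnmt3b passed without control replicate 1 (adjusted p = 0.0251) and with array weights (0.00907). Of the 11 general pluripotency genes none passed, also adjusted over the list alone (median 0.10, adjusted p = 0.494).

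The keratin genes Krt8 and Krt18 fell in mutant cells in ESC medium, at -1.85 (SE 0.11, adjusted p = 2.52e-05) and -2.12 (SE 0.25, adjusted p = 0.00126). Epha1, an ephrin receptor gene, fell by 2.06 (SE 0.24), and Perp, a desmosome gene activated by p53, fell by 0.79 (SE 0.10). Of 20 fibroblast and feeder cell genes, 5 fell and 15 did not pass, and 7 were lower and 2 higher adjusted over the list alone (median -0.08, adjusted p = 0.0254, or adjusted p = 0.391 with an estimated correlation). Tagln, of contractile fibres, fell by 2.23, not called without mutant replicate 2 (0.077), and Col1a1, a collagen gene, fell by 1.32. That list's adjusted p was 0.0595 without control replicate 1 and 0.083 without mutant replicate 3. Of 18 targets of FGF-ERK signalling, 2 fell and 6 were lower adjusted over the list alone (median -0.27, adjusted p = 0.00758, or adjusted p = 0.346 with an estimated correlation). The ERK inhibitor gene Spred1 fell by 0.69 (SE 0.08). Of 19 p53 targets, Perp fell and 3 were lower adjusted over the list alone (median -0.18, adjusted p = 0.0101, or adjusted p = 0.299 with an estimated correlation). Of 12 WNT targets, 2 fell and 3 were lower adjusted over the list alone (median -0.14, adjusted p = 0.0364, or adjusted p = 0.557 with an estimated correlation), a call lost without control replicate 1 (0.0842) or 2 (0.0573) or mutant replicate 2 (0.0732) or 3 (0.0573). Of 20 cholesterol synthesis genes, 2 fell, and 2 were lower and 2 higher adjusted over the list alone (median -0.29, adjusted p = 0.0187, or adjusted p = 0.686 with an estimated correlation), and the list did not pass without mutant replicate 2 (0.181). Imprinted genes moved both ways, with 4 higher and 4 lower of 22, also adjusted over the list alone (median -0.03, adjusted p = 0.494). Plagl1 rose by 1.02, and Igf2 and Phlda2, growth genes of distal chromosome 7, fell, at -1.55 and -1.12.

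The remaining lists were not called in ESC medium. Neural progenitor genes had 2 of 32 higher and 1 lower (adjusted p = 0.259). Tubb3, a tubulin gene on chromosome 8, rose by 1.18 (SE 0.24, adjusted p = 0.0189), the adhesion gene Ncam1 rose by 0.94 (SE 0.20, adjusted p = 0.0211), and Sox11 fell by 1.22. The calls of Tubb3 and Ncam1 were lost without control replicate 2 or 3 or either mutant replicate (0.0593 to 0.194 and 0.0662 to 0.137), and that of Ncam1 also under cyclic loess (0.0544) and with the compared groups alone (0.0936). Trophoblast genes had 2 of 17 lower (adjusted p = 0.259), which were the keratin genes Krt8 and Krt18. Primitive streak and mesoderm genes had 0 of 24 called (adjusted p = 0.493), and primitive and visceral endoderm genes 1 of 25 higher and 3 lower (adjusted p = 0.342). Nodal-SMAD2 targets had 1 of 10 lower (adjusted p = 0.494), LIF-STAT3 targets 3 of 14 higher and 1 lower (adjusted p = 0.493), and glycolysis and hypoxia genes 1 of 25 higher (adjusted p = 0.494). Adjusted over the list alone, these counts were the same for the neural, endoderm, Nodal, LIF and glycolysis lists, and 2 higher and 3 lower for trophoblast. No gene of the MYC and ribosome biogenesis list (27 measured, adjusted p = 0.677) or the cell proliferation list (24 measured, adjusted p = 0.402) passed. The MYC list's median and mean were -0.01 while its test pointed up, and the LIF list's median of 0.01 opposed its mean of -0.03. Under cyclic loess the trophoblast (0.0107), MYC (0.0458) and imprinted (0.0107) lists passed. The glycolysis list passed without mutant replicate 2 (0.0232, upward) and without mutant replicate 3 (0.00117, downward). Of the genes given whatever their values, Sox1, Pax6, Nes, Myc, Mycn, Gata6 and Sox17 were not called, with differences of 0.26, 0.08, -0.84, -0.55, -0.25, 0.01 and 0.12, and Nes passed without control replicate 1 (adjusted p = 0.00833) and, like Sox1 (0.0367), with array weights (0.012). Xist rose by 0.96 (SE 0.21, adjusted p = 0.0242) and turned to -0.54 under cyclic loess. It was not called with a trended prior (0.0907) or without control replicate 2 (0.0812) or 3 (0.0754) or mutant replicate 2 (0.213) or 3 (0.0984).

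In all, 615 genes were higher and 609 lower in mutant cells in ESC medium, and without chromosomes 8, X and Y 268 were higher and 498 lower, which took the share of higher calls from 50.2% to 35.0%. X-linked Efhc2, Nxf3 and Magea4 rose by 3.97, 3.03 and 2.54, Tdpoz3 by 2.33, Dnajc5g by 2.29, Calcoco2 by 2.10 and Smc1b, a meiotic cohesin gene, by 2.08. X-linked Mid1 and Fndc3c1 fell, at -3.34 and -2.08, as did Anxa3 (-2.41), Thbs1 (-2.30) and Prtg (-2.25). Under cyclic loess the values of the 7 genes that rose here were smaller, with 2.50 for Efhc2, 1.63 for Nxf3, 1.04 for Tdpoz3, 1.41 for Dnajc5g and 1.04 for Calcoco2, and Smc1b (0.135) and Fndc3c1 (0.144) were not called. Without mutant replicate 2, Tdpoz3 (0.124), Fndc3c1 (0.117) and Thbs1 (0.131) were not called, nor Fndc3c1 (0.0521) and Thbs1 (0.0824) without mutant replicate 3, nor Fndc3c1 with the compared groups alone (0.0645). The count of 1224 changed to 653 without control replicate 2, 639 without control replicate 3, 304 without mutant replicate 2 and 525 without mutant replicate 3, and array weights gave 3138.

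**Figure D2:**
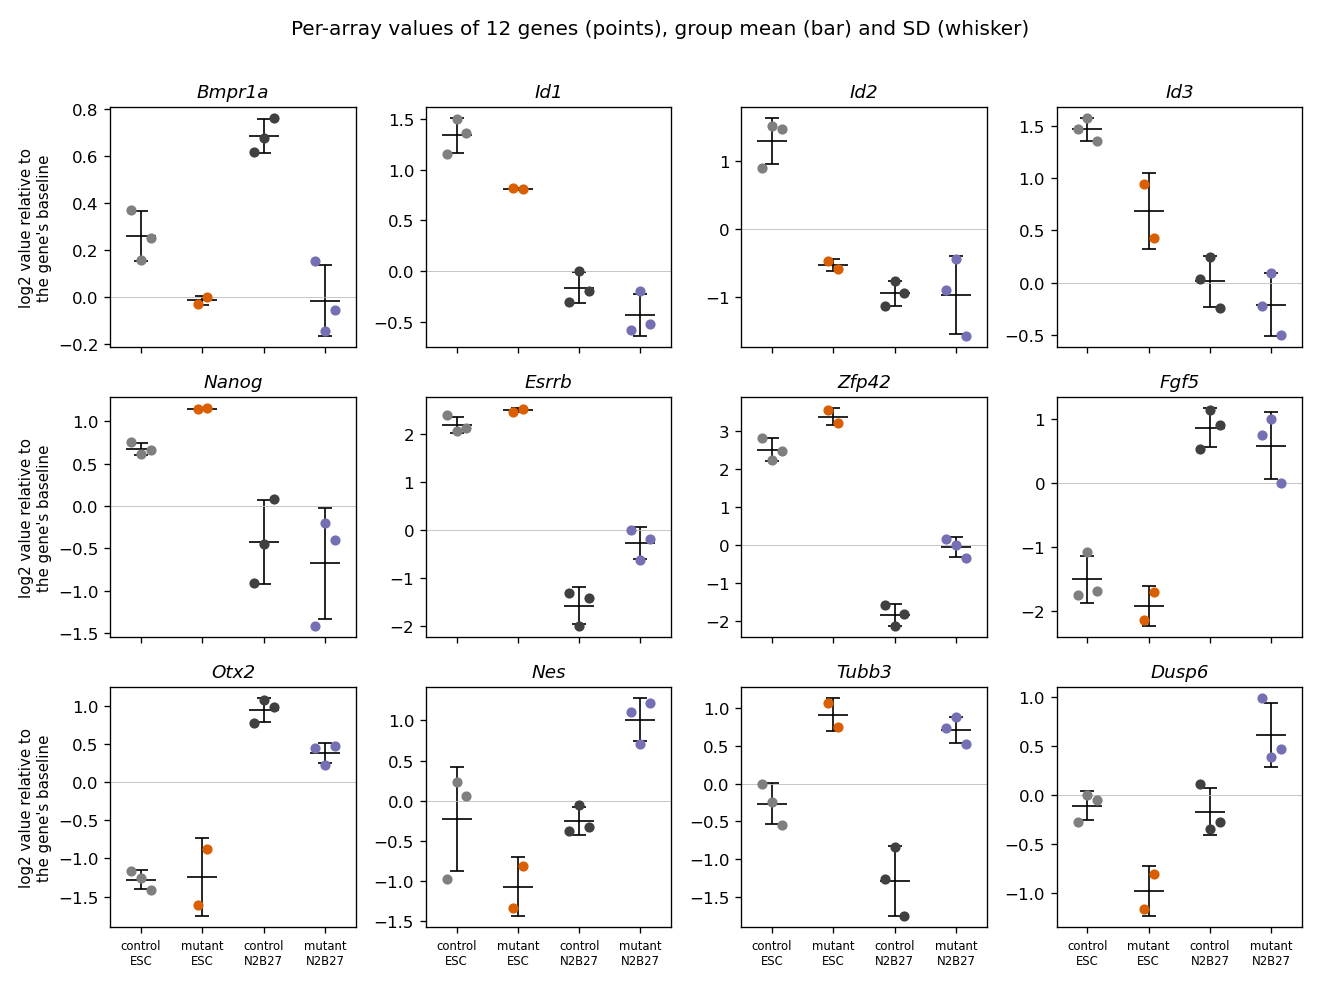
Values of 12 genes on each array as log2 relative to the gene's baseline; points are arrays, the bar is the group mean and the whisker the SD, for control and mutant cells in ESC medium and after 3 days in N2B27. Bmpr1a averages 0.26 and -0.01 in control and mutant cells in ESC medium and 0.68 and -0.01 in N2B27, and Id2 is the one of the 3 Id genes with the widest gap between genotypes in ESC medium.

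How the mutant cells differ from control after 3 days in N2B27 was addressed with 3 arrays of each. Several pluripotency genes were higher in mutant cells. Zfp42 rose by 1.78 (SE 0.19, adjusted p = 0.00129), Esrrb by 1.30 (SE 0.20, adjusted p = 0.0057) and Dppa2, a chromatin factor of pluripotent cells, by 1.58 (SE 0.24, adjusted p = 0.00524). Of 21 naive genes, 6 rose and 15 did not pass, and 14 were higher adjusted over the list alone (median 0.53, adjusted p = 2.05e-09, or adjusted p = 0.155 with an estimated correlation; under cyclic loess the list was not called, at 0.197). Of 11 general pluripotency genes, 3 rose and 5 were higher adjusted over the list alone (median 0.48, adjusted p = 0.00534, or adjusted p = 0.339 with an estimated correlation). Pou5f1, the central pluripotency factor gene, rose by 0.48 (SE 0.10, adjusted p = 0.0266), a call lost without control replicate 1 (0.0721) or 3 (0.0634), under cyclic loess (0.0504) or with the compared groups alone (0.108). Nanog, Sox2 and Klf4 differed by -0.25, 0.15 and 0.22, none called. Zfp42 lies on chromosome 8 and so do Tubb3 and Apela, which rose by 2.01 and 1.79.

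Targets of FGF-ERK signalling were the most widely raised signalling list in N2B27. Of 18, 9 rose, none fell and 12 were higher adjusted over the list alone (median 0.64, adjusted p = 1.16e-07, or adjusted p = 0.118 with an estimated correlation). The transcription factor gene Etv4 rose by 1.26 (SE 0.20, adjusted p = 0.00642) and Spry4, a feedback inhibitor gene, by 1.04 (SE 0.20), the latter not called without control replicate 2 (0.063). Of 19 p53 targets, 6 rose, and 10 were higher and 1 lower adjusted over the list alone (median 0.32, adjusted p = 4.35e-05, or adjusted p = 0.118 with an estimated correlation). The kinase gene Plk2 rose by 1.25 and Perp by 0.50. Of 17 trophoblast genes, 4 rose and 5 were higher adjusted over the list alone (median 0.18, adjusted p = 6e-04, or adjusted p = 0.155 with an estimated correlation), among them Tfap2c by 0.98 and Krt8 by 0.58 (adjusted p = 0.0581 for Krt8 with the compared groups alone), although the imprinted gene Peg10, higher by 1.22, and Krt8 are not confined to trophoblast. Of 27 MYC and ribosome biogenesis genes, 1 rose and 2 were higher adjusted over the list alone (median 0.21, adjusted p = 6e-04, or adjusted p = 0.527 with an estimated correlation). Myc and Mycn differed by 0.68 (adjusted p = 0.221) and 0.83 (adjusted p = 0.0559). Without mutant replicate 3 both passed (0.013 and 0.0433), and Mycn also passed with the replicate block (0.023) and with array weights (0.0377).

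Tubb3, a neuronal tubulin gene, and Gap43, a growth cone gene outside the neural list, rose in mutant cells in N2B27 by 2.01 (SE 0.22) and 1.68 (SE 0.14), and the intermediate filament genes Vim and Nes by 1.25 (SE 0.15, adjusted p = 0.00192) and 1.27 (SE 0.29, adjusted p = 0.0312). Nes lost its call without control replicate 1, 2 or 3 or mutant replicate 1 or 3, with adjusted p from 0.066 to 0.108. Of 32 neural progenitor genes, 4 rose and 1 fell, with 5 and 1 adjusted over the list alone, and the list did not pass (median 0.01, adjusted p = 0.274). Sox1, on chromosome 8, and Pax6, early neural transcription factor genes, differed by -0.09 and -0.10, and Otx2, Fgf5 and Dnmt3b by -0.56, -0.28 and -0.02, none called, though Otx2 passed under cyclic loess (0.0373) and with array weights (0.0438). Of 19 formative and epiblast genes, 1 rose, with 2 higher and 2 lower adjusted over the list alone (adjusted p = 0.838), and the median of -0.05 opposed the mean of 0.06. Primitive streak and mesoderm genes had 0 of 24 called (adjusted p = 0.838), with a median of -0.00 and a mean of 0.05. Primitive and visceral endoderm genes had 1 of 25 lower and none adjusted over the list alone (adjusted p = 0.0593), and passed without control replicate 3 (0.0407) or mutant replicate 2 (0.0398). Gata6 and Sox17 differed by -0.21 and -0.18, not called, and Sox17 passed without mutant replicate 2 (0.0439) and with array weights (0.0305).

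Several genes of the BMP pathway itself were lower in N2B27, while its targets were not called. The lower genes include Bmpr1a, whose fall the genotype itself would give, and the 1 that rose was Gdf3, by 0.77. Of 31 components of the BMP and Activin pathways, 4 fell and 1 rose, with 5 and 1 adjusted over the list alone (median -0.08, adjusted p = 0.0273, or adjusted p = 0.19 with an estimated correlation), among them Bmpr1a and the ligand gene Bmp7 (-0.85, SE 0.12, adjusted p = 0.00462). That list's adjusted p was 0.0575 without control replicate 2 and 0.276 without mutant replicate 2. None of the 19 BMP-SMAD targets passed, also adjusted over the list alone (median -0.04, adjusted p = 0.241). Id1, Id2 and Id3 differed by -0.27, -0.03 and -0.23, and Id1 passed with the replicate block (adjusted p = 0.048) and with array weights (0.0245).

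Imprinted genes moved both ways in N2B27. Of 22, 8 rose and 5 fell, with 10 and 6 adjusted over the list alone (median 0.27, adjusted p = 0.0154, or adjusted p = 0.155 with an estimated correlation). Nnat, a neuronal proteolipid gene, rose by 3.13 (SE 0.13, adjusted p = 2.05e-06), the noncoding RNA gene Rian by 1.58 and Peg10 by 1.22, while Igf2 and Grb10, a growth factor and a growth suppressor gene, fell, at -1.36 and -1.52. The list did not pass without mutant replicate 1 (0.183) or under cyclic loess (0.142). Xist, the noncoding RNA that coats an inactive X chromosome, rose by 4.08 (SE 0.19, adjusted p = 3.29e-06) and read 3.60 to 4.53 in mutant against -0.08 to 0.13 in control. Of 19 germline genes, 4 rose and 1 fell, with 5 and 2 adjusted over the list alone (median 0.21, adjusted p = 0.0166, or adjusted p = 0.376 with an estimated correlation). Rpl10l rose by 1.32, and the other risen genes, which include Rhox9, are X-linked. Without chromosomes 8, X and Y that list did not pass (0.234), nor without control replicate 2 (0.111) or mutant replicate 1 (0.125) or under cyclic loess (0.416).

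Of 25 glycolysis and hypoxia genes in N2B27, 2 fell and 1 rose, with 5 and 1 adjusted over the list alone (median -0.23, adjusted p = 0.00557, or adjusted p = 0.546 with an estimated correlation). Of 24 proliferation genes, 2 fell and 7 were lower adjusted over the list alone (median -0.11, adjusted p = 0.00557, or adjusted p = 0.546 with an estimated correlation), and the list did not pass without control replicate 2 (0.0623) or 3 (0.0616). None of 5 genes from the 2-cell-like list passed and 4 were higher adjusted over the list alone (median 0.48, adjusted p = 0.00557, or adjusted p = 0.376 with an estimated correlation), and the list did not pass without mutant replicate 1 (0.114) or under cyclic loess (0.131). Of 20 cholesterol synthesis genes, Msmo1 rose by 0.70 (not called with the compared groups alone, 0.0509) and Insig1, a feedback inhibitor gene of the pathway, fell by 0.91, with 2 higher and 1 lower adjusted over the list alone. The cholesterol list's adjusted p was 0.0553, and it passed with the replicate block (0.0251) and without control replicate 2 (0.0159) or 3 (0.0158) or mutant replicate 1 (0.00403). Of 14 LIF-STAT3 targets, Stat3 rose by 0.60 (not called with the compared groups alone, 0.0539), with 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.147), and the list passed without control replicate 1 (0.029) or mutant replicate 2 (0.0431). The fibroblast and feeder cell list had 3 of 20 higher and 1 lower, with 4 and 3 adjusted over the list alone (adjusted p = 0.838). No WNT target of 12 (adjusted p = 0.838) and no Nodal-SMAD2 target of 10 (adjusted p = 0.529) passed, and adjusted over the list alone 1 WNT target was higher and 1 lower and 1 Nodal target was higher.

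In N2B27, 817 genes were higher and 327 lower in mutant cells, and without chromosomes 8, X and Y 389 and 221. X-linked Nxf3 rose by 3.04, or by 1.64 under cyclic loess, Trh, a hormone precursor gene, by 2.48 and Dnmt3l by 1.76. X-linked Mid1 fell, at -2.98, as did the DNA polymerase gene Polg (-2.07), Txnip (-1.91), Slc39a8 (-1.85), Colec12 (-1.42) and Greb1l (-1.34). With the compared groups alone, Trh (0.1), Txnip (0.125), Slc39a8 (0.0939) and Greb1l (0.104) were not called. Trh was not called under cyclic loess (0.0707) or without mutant replicate 1 (0.0544) or 2 (0.0521) either. Nor was Txnip without mutant replicate 1 or any 1 control array (0.0675 to 0.113), Slc39a8 without control replicate 2 (0.0742) or 3 (0.106), or Greb1l without control replicate 1 (0.0787) or 2 (0.087). The count of 1144 changed to 712 without control replicate 1, 589 without control replicate 2 and 454 without control replicate 3; it was 397 with the compared groups alone in the fit and 2882 with array weights. Without mutant replicate 2, which stood apart on the third principal component, it was 1204.

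**Figure D3:**
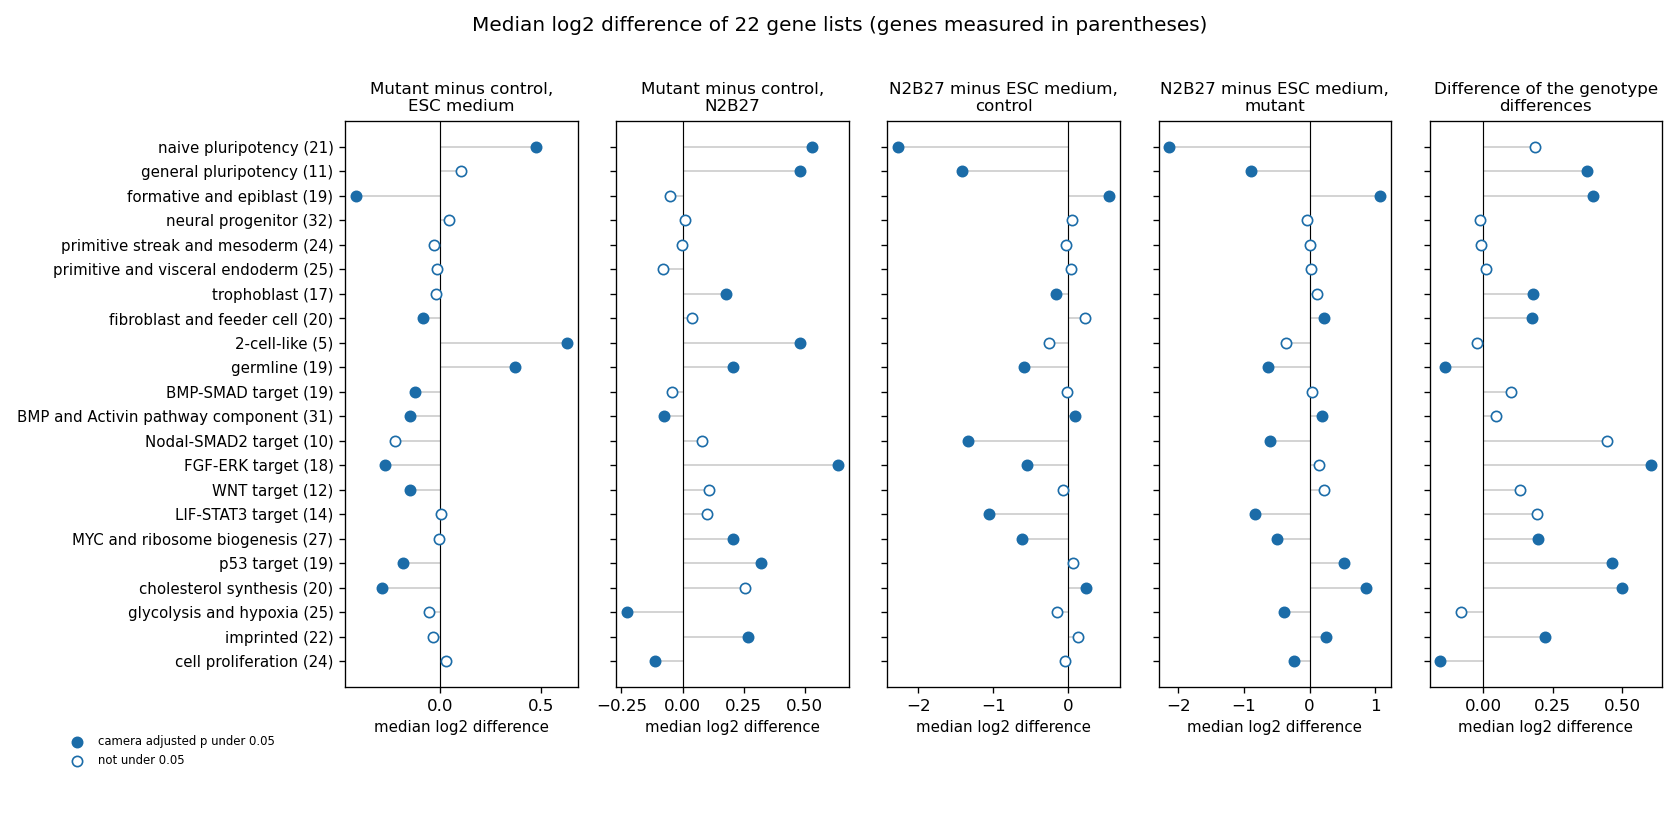
Median log2 difference of the measured members of 22 gene lists in the 5 comparisons; filled points have a camera adjusted p under 0.05 and open points do not, and each panel has its own axis. The naive pluripotency list lies at 0.47 and 0.53 for mutant minus control in ESC medium and N2B27, the former turning under cyclic loess, and at -2.27 and -2.14 for N2B27 minus ESC medium in control and mutant.

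The response of control cells to N2B27 was measured against control cells in ESC medium (n = 3 each). All 21 naive pluripotency genes fell, also adjusted over the list alone (median -2.27, adjusted p = 4.12e-25, or adjusted p = 0.08 with an estimated correlation). Nr0b1, Zfp42, Esrrb and Klf4 had log2 differences of -5.43 (SE 0.20), -4.34 (SE 0.19), -3.77 (SE 0.20) and -2.27 (SE 0.14). Of 11 general pluripotency genes, 9 fell and 1 rose, also adjusted over the list alone (median -1.41, adjusted p = 5.14e-06, or adjusted p = 0.128 with an estimated correlation). Sox2 and Pou5f1 fell, at -1.42 and -0.80. Nanog fell by 1.10 (adjusted p = 0.0229), a call lost without any 1 control array in ESC medium or without control replicate 1 or 2 in N2B27 (0.0543 to 0.085). Of 19 formative and epiblast genes, 11 rose and 3 fell, with 11 and 5 adjusted over the list alone (median 0.55, adjusted p = 0.0113, or adjusted p = 0.44 with an estimated correlation). Fgf5, a marker of the epiblast after implantation, rose by 2.37 (SE 0.28, adjusted p = 0.000243) and Otx2 by 2.23 (SE 0.17, adjusted p = 2.92e-05). Dnmt3b, a DNA methyltransferase gene, rose by 0.40 (adjusted p = 0.0334) and Sox1 by 0.33 (adjusted p = 0.0164). The call of Dnmt3b was lost without control replicate 1 (0.11) or 3 (0.0661) in ESC medium or 1 (0.0862) or 2 (0.113) in N2B27 or with the compared groups alone (0.0511), and that of Sox1 without replicate 1 (0.064) or 2 (0.0523) in ESC medium or 2 (0.0572) in N2B27.

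Most LIF-STAT3 and FGF-ERK targets and most MYC and ribosome biogenesis genes fell in control cells in N2B27. Id1, Id2 and Id3 fell, at -1.51 (SE 0.12), -2.23 (SE 0.25) and -1.46 (SE 0.18). Of all 19 BMP-SMAD targets 5 fell and 1 rose, with 6 and 2 adjusted over the list alone, and the list was not called (adjusted p = 0.095). Of 18 FGF-ERK targets, 10 fell and 1 rose, with 11 and 1 adjusted over the list alone (median -0.54, adjusted p = 2.14e-05, or adjusted p = 0.128 with an estimated correlation). Spry4 fell by 2.62. Of 14 LIF-STAT3 targets, 10 fell and 11 were lower adjusted over the list alone (median -1.06, adjusted p = 2.76e-09, or adjusted p = 0.118 with an estimated correlation). The receptor gene Lifr fell by 1.75. Of 10 Nodal-SMAD2 targets, 6 fell, with 8 lower and 1 higher adjusted over the list alone (median -1.34, adjusted p = 0.00115, or adjusted p = 0.44 with an estimated correlation). The Nodal antagonist gene Lefty2 fell by 2.63. Of 27 MYC and ribosome biogenesis genes, 21 fell and 1 rose, also adjusted over the list alone (median -0.62, adjusted p = 7.96e-10, or adjusted p = 0.219 with an estimated correlation). Myc and Mycn fell, at -2.48 and -2.14. Of 31 BMP and Activin pathway components, 10 rose and 1 fell, with 11 and 1 adjusted over the list alone (median 0.09, adjusted p = 0.0145, or adjusted p = 0.128 with an estimated correlation). Bmp7 rose by 1.92 and Bmpr1a by 0.42 (SE 0.09, adjusted p = 0.00474). Of 19 germline genes, 13 fell, also adjusted over the list alone (median -0.59, adjusted p = 4.49e-06, or adjusted p = 0.128 with an estimated correlation). Rpl10l fell by 2.54. Of 17 trophoblast genes, 5 fell, with 6 lower and 1 higher adjusted over the list alone (median -0.16, adjusted p = 0.00879, or adjusted p = 0.185 with an estimated correlation).

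Of 20 cholesterol synthesis genes, 5 rose and 1 fell in control cells, with 6 and 1 adjusted over the list alone (median 0.24, adjusted p = 0.0491, or adjusted p = 0.685 with an estimated correlation). That call was lost without any 1 control array in ESC medium (0.0515 to 0.071) or without replicate 2 (0.194) or 3 (0.168) in N2B27. The neural progenitor list had 4 of 32 higher and 4 lower, also adjusted over the list alone (adjusted p = 0.47), and Pax6 and Nes differed by -0.06 and -0.03. The primitive streak list had 0 of 24 called (adjusted p = 0.42), and the endoderm list 1 of 25 higher and 1 lower, with 1 and 0 adjusted over the list alone (adjusted p = 0.539). Gata6 and Sox17 differed by 0.14 and 0.24, not called, though Sox17 passed with the replicate block (adjusted p = 0.0384), with the compared groups alone (0.0425) and with array weights (0.0248). Fibroblast genes (5 of 20 higher, 5 lower, adjusted p = 0.411), WNT targets (1 of 12 higher, 3 lower, adjusted p = 0.247), p53 targets (3 of 19 higher, 4 lower, adjusted p = 0.712), imprinted genes (4 of 22 higher, 4 lower, adjusted p = 0.712) and proliferation genes (4 of 24 higher, 4 lower, adjusted p = 0.54) were not called. Adjusted over the list alone these counts were the same apart from fibroblast genes, with 8 higher and 5 lower. The p53 list's median of 0.07 opposed its mean of -0.02. None of the 2-cell-like genes passed (adjusted p = 0.204). Glycolysis and hypoxia genes, with 1 of 25 higher and 5 lower, also adjusted over the list alone, missed the threshold (adjusted p = 0.0781) and passed without control replicate 2 in ESC medium (0.0411) or replicate 2 (0.0424) or 3 (0.0238) in N2B27. Slc39a8 rose by 3.82, Greb1l by 3.18, Bhlhe41 by 2.88, Sema3c by 2.51, Crabp2 by 2.46, Car4 by 2.35, Lrp2 by 2.24 and Tmc7 by 2.23. Jam2, Trh, Zfp640, Tdgf1, Zfp980, Triml2 and Dppa2 fell, at -4.30, -3.94, -3.88, -3.77, -3.59, -3.51 and -3.50. Across all genes, 2554 rose and 2651 fell in control cells in N2B27, and leaving out any 1 array lowered that count of 5205 to between 3987 and 4509.

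The same response in mutant cells compared 3 arrays in N2B27 with 2 in ESC medium. All 21 naive genes fell, also adjusted over the list alone (median -2.14, adjusted p = 2.86e-23, or adjusted p = 0.0843 with an estimated correlation). Nr0b1, Zfp42, Esrrb, Klf4 and Nanog stood at -4.57, -3.44, -2.77, -2.69 and -1.82. Of 11 general pluripotency genes, 9 fell and 1 rose, also adjusted over the list alone (median -0.89, adjusted p = 0.00028, or adjusted p = 0.192 with an estimated correlation). Sox2 and Pou5f1 fell, at -1.46 (SE 0.21) and -0.43 (SE 0.12, adjusted p = 0.0206). Of 19 formative and epiblast genes, 13 rose and 1 fell, with 14 and 1 adjusted over the list alone (median 1.08, adjusted p = 2.49e-07, or adjusted p = 0.0873 with an estimated correlation). Fgf5 rose by 2.51 (SE 0.31), Otx2 by 1.63 (SE 0.19) and Dnmt3b by 0.79 (SE 0.13). Germline genes fell in 11 of 19 and rose in 1, also adjusted over the list alone (median -0.64, adjusted p = 3.35e-07, or adjusted p = 0.0843 with an estimated correlation). Pramel6 fell by 3.70 and Pramel7 fell by 3.30. Pou5f1 lost its call without mutant replicate 2 (0.147) or 3 (0.0658) in ESC medium or 1 (0.0577) or 3 (0.0664) in N2B27, and with the compared groups alone (0.0642).

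Epha1 rose in mutant cells in N2B27 by 2.78 (SE 0.24), Krt8 and Krt18 by 1.94 (SE 0.11) and 2.18 (SE 0.25), and Tagln and Acta2, genes of contractile fibres, by 2.60 (SE 0.36) and 2.45 (SE 0.41). Of 20 fibroblast and feeder cell genes, 7 rose and 8 were higher adjusted over the list alone (median 0.22, adjusted p = 0.00491, or adjusted p = 0.199 with an estimated correlation). Of 19 p53 targets, 11 rose, with 12 higher and 1 lower adjusted over the list alone (median 0.52, adjusted p = 0.00016, or adjusted p = 0.0843 with an estimated correlation). Btg2, an antiproliferative gene, rose by 1.79. Of 20 cholesterol synthesis genes, 10 rose and 1 fell, with 13 and 1 adjusted over the list alone (median 0.86, adjusted p = 0.00016, or adjusted p = 0.489 with an estimated correlation). Hmgcs1, of the mevalonate pathway, rose by 1.09 (SE 0.20). Of 22 imprinted genes, 7 rose and 3 fell, with 13 and 3 adjusted over the list alone (median 0.25, adjusted p = 0.00742, or adjusted p = 0.0873 with an estimated correlation). Nnat rose by 2.53 but turned to -0.33 under cyclic loess, and Rian rose by 1.62. Xist rose by 3.13 (SE 0.21, adjusted p = 1.36e-05) as the X-linked genes fell by a median of 0.0372 relative to autosomes (adjusted p = 0.0202, or adjusted p = 0.244 with an estimated correlation).

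Among BMP targets in mutant cells, Id1 fell by 1.25 (SE 0.14, adjusted p = 0.000163), though by 0.44 under cyclic loess, where it was not called (adjusted p = 0.147). Id3 had -0.90 (SE 0.20, adjusted p = 0.00828), turning to 0.06 under cyclic loess, and Id2 differed by -0.44 (adjusted p = 0.332, but 0.0465 under cyclic loess and 0.00624 with array weights). Bmpr1a differed by -0.00 (SE 0.10, adjusted p = 0.999), and by 0.54 under cyclic loess (adjusted p = 0.00161). The BMP-SMAD list had 4 of 19 lower, also adjusted over the list alone, and was not called (adjusted p = 0.41), with a median of 0.04 against a mean of -0.19. Of 31 BMP and Activin pathway components, 11 rose and 3 fell, with 13 and 3 adjusted over the list alone (median 0.19, adjusted p = 0.00327, or adjusted p = 0.0843 with an estimated correlation). Bmp7 rose by 1.22 and Bmp4 fell by 1.46. Of 14 LIF-STAT3 targets, 9 fell, also adjusted over the list alone (median -0.84, adjusted p = 2.49e-07, or adjusted p = 0.0843 with an estimated correlation). Of 27 MYC and ribosome biogenesis genes, 12 fell and 2 rose, with 17 and 2 adjusted over the list alone (median -0.49, adjusted p = 3.68e-06, or adjusted p = 0.363 with an estimated correlation). Myc fell by 1.25 (adjusted p = 0.0153) and Mycn fell by 1.06 (adjusted p = 0.00993). Of 10 Nodal-SMAD2 targets, 4 fell and 1 rose, also adjusted over the list alone (median -0.60, adjusted p = 0.0427, or adjusted p = 0.609 with an estimated correlation), a call lost without mutant replicate 3 in ESC medium (0.0595) or 1 (0.0697) or 3 (0.124) in N2B27, or under cyclic loess (0.0687). Id3 and Myc lost their calls without mutant replicate 2 in ESC medium (0.108 and 0.129), and Mycn without replicate 3 (0.0832). With the compared groups alone, Myc (0.0722) and Mycn (0.0507) were not called.

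Of 25 glycolysis and hypoxia genes in mutant cells, 6 fell and 1 rose, with 8 and 1 adjusted over the list alone (median -0.39, adjusted p = 0.00122, or adjusted p = 0.489 with an estimated correlation; 0.123 without mutant replicate 3 in ESC medium). Of 24 proliferation genes, 5 fell and 3 were lower adjusted over the list alone (median -0.23, adjusted p = 0.00309, or adjusted p = 0.505 with an estimated correlation). Lists not called were neural progenitor (9 of 32 higher, 3 lower, adjusted p = 0.514), primitive streak (2 of 24 higher, 1 lower, adjusted p = 0.809), endoderm (5 of 25 higher, 1 lower, adjusted p = 0.699), trophoblast (4 of 17 higher, 3 lower, adjusted p = 0.483), FGF-ERK (5 of 18 higher, 1 lower, adjusted p = 0.41), WNT (3 of 12 higher, 1 lower, adjusted p = 0.458) and 2-cell-like (0 of 5, adjusted p = 0.151). Adjusted over the list alone these counts were the same except 0 for the primitive streak, 5 and 3 for trophoblast and 6 and 1 for FGF-ERK. The 2-cell-like list, with a median of -0.36, passed without mutant replicate 3 in ESC medium (0.0334) or 1 in N2B27 (0.0122), and turned upward and passed under cyclic loess (0.0188). The neural list's median of -0.03 opposed its mean of 0.18, and the primitive streak list's median of 0.01 opposed its test. Nes rose by 2.08 (SE 0.32, adjusted p = 0.00103), and Sox1, Pax6, Gata6 and Sox17 differed by -0.03, -0.25, -0.09 and -0.06, not called. Kif1a rose by 3.58, Car4 by 3.45, Fndc3c1 by 3.21, Ccn1 by 3.19, Lpar6 by 3.08, Sema6a by 3.07, Thbs1 by 3.02 and Lrp2 by 2.78, while Kif1a and Fndc3c1 had 0.90 and 1.03 under cyclic loess. Jam2, Lefty2, Tcl1, Calcoco2, Septin1 and Zfp640 fell, at -3.98, -3.42, -3.41, -3.20, -3.17 and -3.16. Across all genes, 2971 rose and 2047 fell in mutant cells; the count of 5018 became 2720 without mutant replicate 2 in ESC medium and 7689 with array weights.

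Whether the genotype difference itself changed with the medium was tested by the interaction, the difference in N2B27 minus that in ESC medium, over all 11 arrays. Targets of FGF-ERK signalling had a genotype median of -0.27 in ESC medium, with 2 of 18 called, and of 0.64 in N2B27, with 9 called, and both list calls were lost with an estimated correlation (adjusted p = 0.346 and 0.118). Of the 18, 6 had a positive interaction and 10 adjusted over the list alone (median 0.61, adjusted p = 7.33e-11, or adjusted p = 0.0399 with an estimated correlation). Spry2 had an interaction of 1.61 (SE 0.25, adjusted p = 0.0143) and Dusp6, a phosphatase gene that restrains ERK, of 1.66 (SE 0.27, adjusted p = 0.0145). Krt8 had an interaction of 2.43 (SE 0.15, adjusted p = 7.99e-05), Epha1 of 2.60 (SE 0.32, adjusted p = 0.00507) and Perp of 1.28 (SE 0.14, adjusted p = 0.00242). Pramel6 and Pramel7 had -3.65 (SE 0.17) and -3.28 (SE 0.20), and Dnajc5g -2.15 (SE 0.08, adjusted p = 3.77e-06). Xist had 3.13 (SE 0.28, adjusted p = 0.000981) while X-linked genes moved by a median of -0.0799 relative to autosomes (adjusted p = 9.78e-08, or adjusted p = 0.0112 with an estimated correlation). Id2 had 1.79 (SE 0.38, adjusted p = 0.0447) and Nes 2.11 (SE 0.43, adjusted p = 0.0367). Spry2 lost its call without mutant replicate 2 (0.0631) or 3 (0.0676) in ESC medium and Dusp6 without mutant replicate 2 (0.0943). Id2 did without any 1 of control replicates 2 and 3 or either mutant array in ESC medium or control replicates 1, 2 and 3 or mutant replicate 1 in N2B27 (0.0757 to 0.165). Nes did without the same arrays or mutant replicate 3 in N2B27 (0.0652 to 0.186). Under cyclic loess Spry2 (0.113), Id2 (0.173) and Nes (0.058) were not called.

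Some other called lists had positive medians. Of 19 p53 targets, 3 were positive, with 10 positive and 1 negative adjusted over the list alone (median 0.46, adjusted p = 2e-07, or adjusted p = 0.0399 with an estimated correlation). Of 17 trophoblast genes, 3 were positive and 6 adjusted over the list alone (median 0.18, adjusted p = 0.000125, or adjusted p = 0.0785 with an estimated correlation). Of 22 imprinted genes, 5 were positive and 6 adjusted over the list alone (median 0.22, adjusted p = 0.000735, or adjusted p = 0.0571 with an estimated correlation). Nnat had 2.33 (SE 0.19, adjusted p = 0.000681) and Peg10 1.55 (SE 0.18). Of 19 formative and epiblast genes, 3 were positive and 6 adjusted over the list alone (median 0.39, adjusted p = 8.84e-05, or adjusted p = 0.286 with an estimated correlation). Of 20 fibroblast genes, 2 were positive and 3 adjusted over the list alone (median 0.18, adjusted p = 0.00661, or adjusted p = 0.289 with an estimated correlation; 0.0548 without mutant replicate 3 in N2B27). Of 20 cholesterol synthesis genes none passed, with 5 positive and 1 negative adjusted over the list alone (median 0.50, adjusted p = 0.000943, or adjusted p = 0.65 with an estimated correlation). Nnat was not called under cyclic loess.

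The remaining list calls of the interaction rested on few or no single genes. None of 11 general pluripotency genes passed, also adjusted over the list alone (median 0.37, adjusted p = 0.0396, or adjusted p = 0.648 with an estimated correlation), and the call was lost without control replicate 1 (0.12) or 2 (0.0599) or mutant replicate 3 (0.0886) in ESC medium or control replicate 1 (0.0663) or mutant replicate 1 (0.139) or 2 (0.157) in N2B27. None of 27 MYC and ribosome biogenesis genes passed, also adjusted over the list alone (median 0.20, adjusted p = 0.0156, or adjusted p = 0.742 with an estimated correlation), a call lost without mutant replicate 3 in ESC medium (0.112) or control replicate 1 (0.152) or mutant replicate 2 (0.169) in N2B27. None of 24 proliferation genes passed, also adjusted over the list alone (median -0.15, adjusted p = 0.00181, or adjusted p = 0.648 with an estimated correlation). Of 19 germline genes 1 was negative, Sycp1 at -1.09, with 5 negative and 2 positive adjusted over the list alone (median -0.14, adjusted p = 0.0183, or adjusted p = 0.517 with an estimated correlation). The germline call was lost without mutant replicate 2 in ESC medium (0.0631) or control replicate 1 (0.152) or mutant replicate 2 (0.0598) or 3 (0.0584) in N2B27, and the call of Sycp1 was lost without mutant replicate 2 in ESC medium (0.0597). Under cyclic loess the general pluripotency (0.139), germline (0.661) and MYC (0.665) lists were not called.

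Other lists had no interaction call. These were naive pluripotency (0 of 21, adjusted p = 0.489, called under cyclic loess at 0.00693), neural progenitor (3 of 32 positive, adjusted p = 0.924), primitive streak (0 of 24, adjusted p = 0.761), endoderm (1 of 25 negative, adjusted p = 0.882), 2-cell-like (0 of 5, adjusted p = 0.761), BMP-SMAD targets (1 of 19 positive, adjusted p = 0.235), BMP and Activin components (0 of 31, adjusted p = 0.653) and Nodal targets (0 of 10, adjusted p = 0.324). WNT targets (1 of 12 positive, adjusted p = 0.0606), LIF-STAT3 targets (0 of 14, adjusted p = 0.837) and glycolysis genes (0 of 25, adjusted p = 0.0606) were not called either. Adjusted over the list alone, positive and negative counts were 5 and 2 for naive pluripotency, 1 and 0 for the primitive streak, 2 and 3 for BMP and Activin components, 1 and 0 for Nodal, 4 and 0 for WNT and 2 and 2 for LIF, and the same as above for the others. The WNT list passed without control replicate 3 in ESC medium (0.0468) or mutant replicate 1 in N2B27 (0.0185), and the glycolysis list without control replicate 3 (0.0185) or mutant replicate 2 (3.84e-06) in ESC medium or control replicate 1 in N2B27 (0.00481). Median and mean differed in sign for the neural list (-0.01 and 0.14) and the primitive streak list (-0.01 and 0.14), and the endoderm list's median of 0.01 opposed its test. Bmpr1a had an interaction of -0.42, Id1 and Id3 of 0.26 and 0.56, Nanog, Pou5f1, Sox2, Klf4, Zfp42 and Esrrb of -0.72, 0.37, -0.04, -0.43, 0.90 and 1.00, none called. Fgf5, Otx2, Dnmt3b, Sox1, Pax6, Myc, Mycn, Gata6 and Sox17 had 0.14, -0.60, 0.39, -0.35, -0.18, 1.23, 1.09, -0.23 and -0.30, none called. Under cyclic loess Esrrb (0.0249) and the BMP-SMAD (0.0303), WNT (0.0158) and glycolysis (0.0303) lists passed, and the 2-cell-like list turned and passed (0.0158). Klf4 passed without control replicate 1 in ESC medium (0.0177) and Myc without mutant replicate 3 in N2B27 (0.0194). With array weights, Bmpr1a (0.0085), Esrrb (0.0215) and Mycn (0.0365) passed.

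Across all genes, 312 had a positive and 110 a negative interaction. The count of 422 became 171 without control replicate 2, 183 without control replicate 3, 59 without mutant replicate 2 and 162 without mutant replicate 3 in ESC medium, 199 and 196 without control replicates 2 and 3 and 633 without mutant replicate 2 in N2B27, 280 under cyclic loess, 652 with the random block of genotype and number and 1782 with array weights.

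The genotype differences in both media shared part of their direction across genes. Pearson's r between them was 0.358 over 19935 genes (Spearman's rho 0.259), from comparisons without shared arrays, and genes are not independent replicates. Of the genes higher in mutant cells, 205 were shared against 25.2 for independent lists, and of those lower 61 against 9.99. Many higher calls lay on chromosomes 8, X and Y. The count for independent lists is therefore too low a baseline for them, and sharing without these chromosomes was not counted. The medium responses of both genotypes had r = 0.787 (rho 0.673), with 1747 genes that rose in both against 381 for independent lists and 1469 that fell in both against 272. The genotype difference in ESC medium ran against the medium response of control cells, with r = -0.254. These comparisons share the 3 control arrays in ESC medium, too few to be split, and 100 simulated unchanged groups gave a mean r of 0.449. The covariance was -0.0287 against 0.00727 simulated, a difference of -0.0359. Of genes higher in mutant cells in ESC medium, 238 fell in control cells in N2B27 against 81.8 for independent lists, and of those lower 236 rose against 78.0, although counts for independent lists do not hold where arrays are shared.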

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

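The tests for a single deviating chromosome 8 array, for male cells in the mutant cultures and for the sex chromosomes behind the FGF-ERK list, and the fits without chromosomes 8, X and Y, were chosen after the results were seen.

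What drew attention to the results below is that the genotype difference in N2B27 differed from that in ESC medium by the interaction test, which called 422 genes. The largest positive values were Xist 3.13, Has2 2.69, Epha1 2.60, Krt19 2.58 and Krt8 2.43, and the largest negative ones Pramel6 -3.65, Pramel7 -3.28, Efhc2 -2.39, Dnajc5g -2.15 and Magea4 -2.03. Without mutant replicate 2 in ESC medium, the calls of Has2 (adjusted p = 0.119), Krt19 (0.0862), Magea4 (0.0713) and Efhc2 (0.0528) were lost, and that of Has2 also without mutant replicate 3 (0.0676) or control replicate 2 (0.0554) or 3 (0.0568) there. Gene lists that differed between media had median interactions of 0.37 (general pluripotency), 0.39 (formative and epiblast), 0.18 (trophoblast), 0.18 (fibroblast and feeder cell), -0.14 (germline), 0.61 (FGF-ERK), 0.20 (MYC and ribosome biogenesis), 0.46 (p53), 0.50 (cholesterol synthesis), 0.22 (imprinted) and -0.15 (cell proliferation). With an estimated correlation, only the FGF-ERK and p53 lists kept their call (adjusted p = 0.0399 each), and the other 9 had from 0.0571 (imprinted) to 0.742 (MYC). Genes of the X chromosome had -0.0799 relative to the autosomes.

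Chromosome 8 genes were higher in mutant cells in both media. A single deviating array is argued against, since on all 5 mutant arrays the chromosome 8 median exceeded every autosome median of the control arrays. That bar is low, as the deviations are taken from the control mean, which holds control arrays near 0. However, the chromosome 8 medians of 0.133 to 0.189 also lie above every other autosome of a mutant array, at most 0.0493. A copy-number difference of chromosome 8 between the lines would raise genes along its whole length, and in each medium all 10 of 10 bins of neighbouring genes lay above the upper end of the middle 95% of autosome bins. The values are consistent with such a difference, which is a hypothesis, as no DNA was measured. An effect of the loss of Bmpr1a on the genes of this chromosome stays open, because every mutant array differs from every control array in both.

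X-linked genes were higher in mutant cells, more so in ESC medium than in N2B27, and Xist was higher in both media, by 0.96 and 4.08, the former turning to -0.54 under cyclic loess. A share of male cells that rose from ESC medium to N2B27 is argued against by Y-linked Eif2s3y, which differed by -0.0647 (SE 0.11) between media in mutant cells while it lay 4.20 below control in N2B27. A small constant share of male cells cannot be told apart from none, because the range of Eif2s3y over the 5 mutant arrays, 0.195, would be narrow in both cases. An X dosage above that of control cells in ESC medium, as from 2 active X chromosomes, is consistent with 8 of 10 bins of neighbouring X-linked genes lying above the upper end of the middle 95% of autosome bins. Eif2s3y read -3.73 to -3.54 on the 5 mutant arrays and 0.37 to 0.72 on the control arrays, and Uty was lower too. Kdm5d, Srsy, Sry, Usp9y and Zfy2 were not called. Losing Bmpr1a, a gene of chromosome 14, would not take away Y-linked transcripts. These values argue against the mutation as the whole source of the difference in sex chromosomes. Whether the mutation adds to the X dosage stays open, and the labels give no sex for the mutant lines.

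FGF-ERK targets had a median of -0.27 in mutant cells in ESC medium, with 2 of 18 called, and of 0.64 in N2B27, with 9 called, list calls that were both lost with an estimated correlation (0.346 and 0.118). Members on chromosomes 8, X and Y are argued against as the whole cause, since the interaction without those chromosomes had an adjusted p of 5.57e-10. A single deviating array is argued against at the preset correlation only (adjusted p at most 1.46e-07 without each of 11 arrays). The sex chromosomes of the lines cannot be told apart from the loss of Bmpr1a, because 0 control arrays had Y-linked Eif2s3y within the range of the mutant arrays. An effect of the loss of Bmpr1a on this signalling stays open for the same reason.

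Of the 10 splits of the 6 arrays into 3 and 3, only the real one called 1144 genes between genotypes in N2B27. The others called at most 9. Between media in control the real one called 5205 and the others 0. The others that part all 3 pairs of sample numbers called 0 in both. These are too few splits for a share under 0.05. Wrong splits mix both groups, so the real difference lowers their counts, which give no chance level.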

How the results depend on the processing

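Fits without chromosomes 8, X and Y, with genes of 1 cluster or each cluster on its own, and list tests under median centring, cyclic loess or without those chromosomes were chosen after the data were seen. The brightest cluster of a gene and the filter on dim probes were not run, as centred values hold no signal over background. Of 350 calls of named genes, 210 held in every alternative fit. The cause was not tested unless given. Without each array in turn, counts ran from 304 to 1428 for genotype in ESC medium (main 1224), 454 to 1204 in N2B27 (1144), 3987 to 4509 for medium in control (5205), 2720 to 5956 in mutant (5018) and 59 to 633 for the interaction (422); a lone mutant array in ESC medium is then assumed to vary like the other groups. In the same order, adjusted p under 0.01 left 466, 320, 3062, 3072 and 72, and a 2-fold change 193, 124, 692, 1000 and 155, by construction. Array weights gave 3138 and 2882 for genotype, 7689 for medium in mutant and 1782 for the interaction. Without chromosomes 8, X and Y, 766 and 610 genes differed by genotype, with 35.0% higher in ESC medium against 50.2%. The compared groups alone gave 397 in N2B27. The interaction had 657 with the replicate block, 652 with the random block and 280 under cyclic loess. Where numbers pair the arrays, the block added calls of Eomes (0.0306), Tmem92 (0.00971), Usp17la (0.0486) and Rnf43 (0.029) for genotype in N2B27 and of Tcstv3 (0.0122) and Tmem92 (0.0437) for medium in control, besides those given above, and it changed no other call there. Elsewhere the arrays share only a number. There the block gave calls of Id1 (0.00322), Dnmt3b (0.043), Dppa2 (0.0478), Tmem92 (0.00857) and Usp17lc (0.0173) for genotype in ESC medium, of Tcstv3 (0.00781), Usp17lc (0.0125) and the 2-cell-like list (0.00793) for medium in mutant, and of Id3 (0.0415), Esrrb (0.029), Eomes (0.0398), Dppa2 (0.0455), Msmo1 (0.0274), Stat3 (0.034), Ndrg1 (0.0365) and the WNT list (0.0437) for the interaction. It gave no call of Col4a1 in ESC medium (0.0507) or of the Nodal list for medium in mutant (0.0901). With the random block Id1 passed in ESC medium (0.0396).

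Genotype effects of both media had r = 0.358, but 0.388 under cyclic loess, 0.257 without chromosomes 8, X and Y, and 0.312 to 0.366 without each array. Medium effects had 0.756 to 0.795, and genotype in ESC medium with medium in control -0.289 to -0.179. With an estimated correlation, 0 lists passed in each comparison but the interaction, with 2, where fry passed 4. The glycolysis list in ESC medium had 0.00117 to 0.993 without each array and turned, at 0.0232, without mutant replicate 2. Cyclic loess takes the mean of centred values for brightness, so its reversals may rest on its construction, which was not tested. It turned the naive (0.0892) and 2-cell-like (0.183) lists in ESC medium and the latter for medium in mutant (0.0188) and the interaction (0.0158). In ESC medium it turned Tcl1 to -0.072, Zfp42 to -0.29, Klf4 to -0.49, Bcl3 to -0.39 and Xist to -0.54, and Nr0b1 to -0.11 in N2B27. For medium in mutant it turned Nnat to -0.33, Bmpr1a to 0.54 and Id3 to 0.065. Bmpr1a had -0.72 under it in ESC medium, and -0.70 in N2B27, under a 2-fold change.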

Other observations

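The genes of this part were chosen after their values were seen. Cald1, which encodes an actin-binding regulator of contraction, had a log2 difference between mutant and control cells in ESC medium of -1.91 (SE 0.24, adjusted p = 0.00184), and the tropomyosin gene Tpm2 had -1.12 (SE 0.15, adjusted p = 0.00223). The fibroblast and feeder cell markers Tagln, Acta2 and Col1a1 fell in the same comparison, at -2.23, -1.88 and -1.32, though Tagln was not called without mutant replicate 2 (0.077) nor Acta2 without any 1 of the 5 arrays (0.0508 to 0.161). Cldn6, a claudin gene of early epithelia, had -1.79 (SE 0.22, adjusted p = 0.00149). In N2B27 the genotypes were close in Cldn6 (0.08) and Cald1 (-0.24), with neither called. When mutant cells moved to N2B27, Cald1 rose by 2.53 and Cldn6 by 2.32, and the interaction of Cldn6 was 1.87 (SE 0.29, adjusted p = 0.0141). Tap1, a peptide transporter gene of antigen presentation, rose in N2B27 in control by 0.78 (SE 0.11, adjusted p = 0.000664) and in mutant cells by 1.88 (SE 0.12, adjusted p = 1.34e-05). B2m, the light chain gene of class I molecules, rose by 1.95 in control and 2.33 in mutant cells, the latter not called without mutant replicate 2 in ESC medium (adjusted p = 0.0687).

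In the imprinted cluster on chromosome 12, Meg3 and Rian, noncoding RNA genes expressed from the maternal allele, rose in mutant cells in N2B27 by 1.26 (SE 0.19, adjusted p = 0.0057) and 1.58 (SE 0.18, adjusted p = 0.00173), and the paternally expressed Rtl1 rose by 0.59 (SE 0.08, adjusted p = 0.0032). The paternally expressed Dlk1 differed by -0.12 (SE 0.12, adjusted p = 0.676). Meg3 was not called under cyclic loess (adjusted p = 0.23). Among X-linked genes with a counterpart on the Y, Eif2s3x was higher in mutant cells by 0.65 (SE 0.07, adjusted p = 0.000678) in ESC medium and 0.34 (SE 0.06, adjusted p = 0.0115) in N2B27, while Eif2s3y had -4.18 and -4.20. With the compared groups alone, Eif2s3x was not called in N2B27 (0.0603).

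On the mutant arrays in N2B27, the median of chromosome 11 genes relative to the other autosomes was 0.0462 and 0.0493 for replicates 2 and 3 and 0.00281 for replicate 1.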
